A study of Escherichia coli with 12 samples.

How the data were processed

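The study measured RNA in 12 cultures of E. coli MG1655, 3 for each of 4 genotypes (control, recA730, oxyRc and the oxyRc recA730 double mutant). The labels state that the cultures of a genotype were separate, so the spread between replicates covers culture and library preparation. RNA was made into libraries with a stranded mRNA kit, per the labels' protocols. Reads were aligned with Bowtie2 2.5.2, handled with SAMtools 1.18 and counted per gene with featureCounts 1.5.0 on assembly ASM584v2, per the submitters' processing notes, which also name edgeR 4.2.2. The strand setting and the treatment of reads that map to several places are not given in the sources used here. This matters for genes that overlap, lie opposite each other or have near-identical copies, whose values are uncertain.

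The deposited values are whole-number counts of reads per gene, 1 value per gene and library, and were not normalized by the authors, as seen from totals that differ between libraries. They cover 4639 genes, of which 4288 are protein-coding, 97 are non-coding RNA genes, 22 are ribosomal RNA genes, 86 are transfer RNA genes, 145 are pseudogenes and 1 is of another type. All 4639 locus tags matched the gene table of ASM584v2, from which symbols and coordinates were taken. Library totals ran from 8068570 to 20487694 counts, with 69.6% to 74.9% on ribosomal RNA. Replicate libraries were compared before averaging: none held identical values, and the chi-square per degree of freedom over genes ran from 3.51 to 5.78 among the oxyRc libraries and from 19.5 to 74.6 within the other genotypes, so each counted as a replicate. The oxyRc cultures were closer to each other. Floors in the text cover counting error only.

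Each of the 6 comparisons (5 pairs of genotypes and the interaction) came from 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) to all 12 libraries, with a mean per genotype and no covariate. Genes were kept by filterByExpr with a minimum count of 10, which left 4211 and removed 428. TMM scaling gave factors from 0.897 to 1.159, and the common biological coefficient of variation was 0.218. Robust glmQLFit and glmQLFTest were used, with Benjamini-Hochberg adjustment over the 4211 genes and a threshold of 0.05. The SE of a log2 fold change was its absolute size divided by the square root of F, and its 95% interval came from the t distribution of the fit. Tests were 2-sided. With 3 cultures against 3 the smallest exact permutation p is 0.1, so single genes were tested only through the fit shared by all genes.

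A total of 24 gene lists (564 entries, all matched, 8 by an older symbol) were fixed before the data were examined, together with the groups, the tests, the rule for naming genes and the processing alternatives. They were the SOS regulon, the translesion polymerases, OxyR-activated and OxyR-repressed genes, Fur-repressed iron uptake, SoxRS, Isc assembly, RpoS general stress, acid resistance, heat shock, cold shock, flagella, ribosomal proteins, replication and repair, the e14, Rac and Qin prophages, cysteine and sulfate assimilation, the TCA cycle, anaerobic respiration, amino acid biosynthesis, envelope stress, and the chromosomal neighbours of recA and of oxyR (each with the gene itself). Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1), adjusted over lists within a comparison. Members were counted as passing over all genes and adjusted over the list alone.

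Named genes were recA, lexA and oxyR, then for the first 4 comparisons the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between the libraries of the 2 genotypes, and 5 of each for the other comparisons (overlap allowed for the interaction). Up to 4 members of each list with the smallest p were added. Members named outside this rule, such as SOS genes that did not pass, members of short counts, yijF, flgC, jayE, ymfQ and genes in the part on other observations, were chosen after their values were seen.

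Folds against a group with 0 counts in all 3 libraries are bounds from a floor of 3 counts over the group. The fit was tested on simulated counts for recA730 against control (4211 genes, seeded changes): it recovered 61 of 66 genes changed 4-fold, 40 of 67 changed 2-fold and 7 of 67 changed 1.5-fold, with 0 of the wrong sign, and 8 of its 116 calls were false. Changes were placed only in genes above a minimum expected count, and counts were drawn independently for each gene. Each gene had 1 spread for all genotypes, although the real oxyRc libraries were closer to each other than those of control and recA730. The rates therefore do not cover changes in low-count genes, shifts shared between genes or unequal spread between genotypes. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors or library totals as scaling, omission of ribosomal and transfer RNA genes, no filter or a filter of 10 CPM in 3 libraries, the replicate number as a block, a fit of only the genotypes compared, adjusted p under 0.01, a 2-fold limit, and each library left out in turn. A fit without the 26 e14 genes, and the alternatives for counts of list members, were added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.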

Results

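Messenger RNA levels were measured by RNA sequencing in 4 genotypes of Escherichia coli K-12 MG1655, each grown as 3 separate cultures, which gave 12 libraries. The genotypes were a control strain, a recA730 mutant, an oxyRc mutant and the double mutant that carries both alleles. RecA730 is a form of the recombinase RecA that is active without DNA damage, so that the repressor LexA is cleaved and the SOS (DNA damage) genes are expressed during normal growth. The oxyRc allele encodes a form of OxyR, the peroxide-sensing transcription factor, that is active without peroxide. Cells were harvested from 20 mL LB cultures at 37 °C and an OD600 of 0.5. The title of the series places the comparison between the OxyR response and SOS mutagenesis at the centre of the study.

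The control libraries held 14804182, 20487694 and 15285997 counted reads in replicates 1, 2 and 3. The recA730 libraries held 9859340, 14440174 and 10174418, the oxyRc libraries 8068570, 11514121 and 10874986, and the double-mutant libraries 15191672, 14572180 and 12474639. Ribosomal RNA took 69.6% to 74.9% of the counts, so that 2139279 to 5380169 counts per library fell on protein-coding genes. Levels are given in CPM after TMM scaling, over all counted reads with ribosomal RNA included, as mean ± SD over 3 cultures, and fold changes as log2 values ± SE. Principal components 1, 2 and 3 held 36.2%, 22.0% and 15.8% of the variance of the log2 CPM values.

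The altered genes were examined first. The recA transcript (b2699, chromosome position 2822708 to 2823769 of assembly ASM584v2) stood at 146 ± 29.7 CPM in the control, 3061 ± 502 in recA730, 144 ± 4.37 in oxyRc and 2222 ± 650 in the double mutant (SD, n = 3 each). Its level was therefore high in every library with the recA730 allele, with a log2 fold change of 4.39 ± 0.24 in recA730 against control (adjusted p = 2.19e-07). The lexA transcript (b4043, 4257115 to 4257723), which LexA itself represses, was at 66.8 ± 14.5 CPM in the control and 243 ± 7.51 in recA730, and at 79.1 ± 4.11 in oxyRc and 235 ± 34.0 in the double mutant. The oxyR transcript (b3961, 4158490 to 4159407) was at 40.8 ± 1.62, 34.2 ± 1.67, 39.2 ± 2.95 and 32.1 ± 4.25 CPM in the same order of genotypes, and did not differ between oxyRc and control (log2 fold change -0.06, adjusted p = 0.838). The oxyRc allele alters the activity of the protein, so the amount of its transcript does not check that label. The transcript of katG, an OxyR target, was at 6083, 5617 and 6460 CPM in the oxyRc libraries and at 88.9, 79.4 and 86.7 CPM in the control libraries.

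In recA730 against control, which asks what the recA allele does on its own, the SOS genes rose together. Of the 35 measured members of the SOS list, 31 rose and none fell, with 31 also rising when adjusted over the list alone, and their median log2 fold change was 2.51. Among the genes of the translesion polymerase DNA polymerase V, umuD rose from 0.756 ± 0.242 to 70.2 ± 12.7 CPM (log2 fold change 6.49 ± 0.34) and umuC from 4.25 ± 0.318 to 174 ± 37.8 CPM (5.35 ± 0.27). The other translesion polymerase genes on the list, polB (2.40 ± 0.14) and dinB (3.11 ± 0.21), also rose, so that 4 of 4 members of that sublist passed the test and 4 did when adjusted over the list alone. Large rises were also seen for tisB, a membrane toxin gene (6.12 ± 0.29), recN, a double-strand break repair gene (4.77 ± 0.22), recX, a RecA inhibitor gene (4.21 ± 0.23), and yebF (4.42 ± 0.31). The SOS members yafQ (0.23), dinJ (0.21), hokE (0.82) and ybfE (-0.06) did not pass. The list test by camera gave an adjusted p of 7.78e-191 for the SOS list, and the call held with an estimated correlation (adjusted p = 0.000277).

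**Figure D1:**
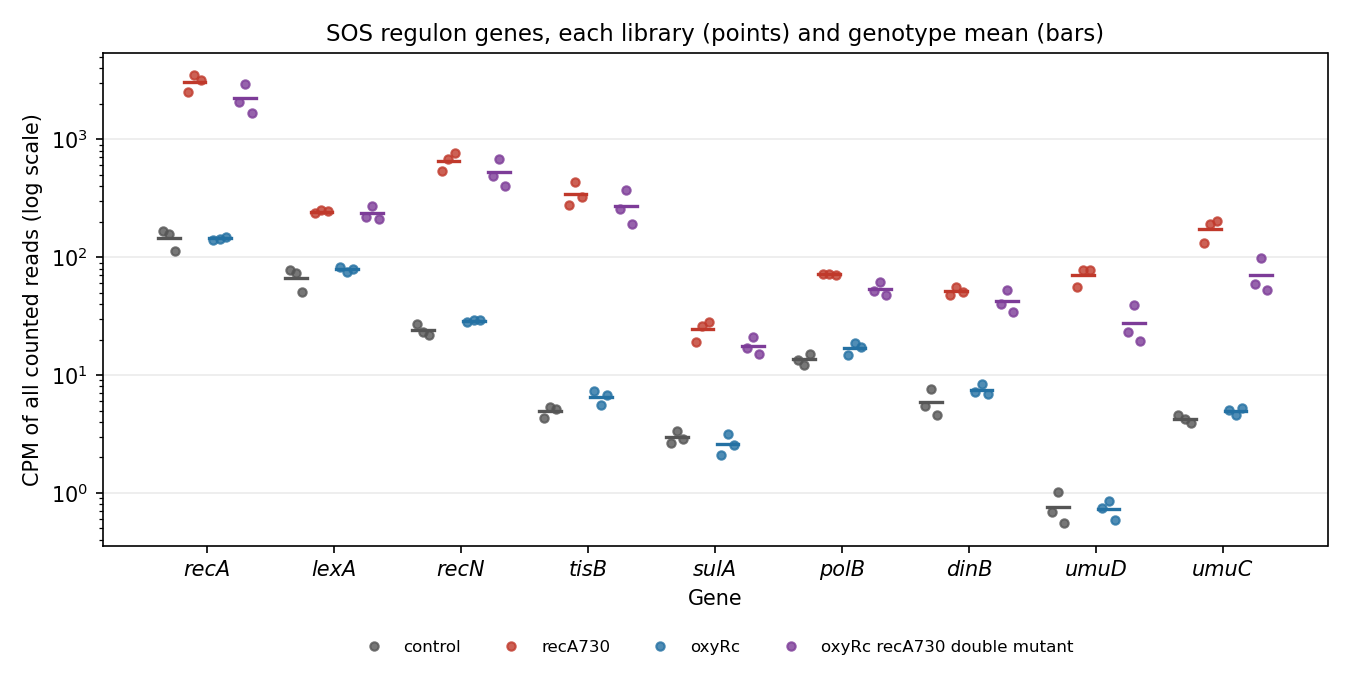
CPM on a log axis of recA, lexA and 7 other SOS genes in each of the 12 libraries (points) with the mean of each genotype (bars). umuC has a mean of 4.25 CPM in the control, 174 CPM in recA730 and 70.0 CPM in the double mutant, and recA has means of 146, 3061 and 2222 CPM.

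Outside the e14 prophage, the furthest falls in recA730 were in the sorbitol (srl) operon, which lies near recA on the chromosome: srlD (b2705, 2827737 to 2828516) went from 189 ± 26.7 to 4.72 ± 1.16 CPM (log2 fold change -5.33 ± 0.19, adjusted p = 1.27e-08) and srlB by -5.28 ± 0.23. srlR (-1.81) and srlA (-1.60) fell less. srlD and srlB were low in every library with the recA730 allele. The counts do not separate an effect of the allele from that of a marker linked to recA. Of the 15 measured genes of the list around recA, which includes recA itself and the SOS gene recX, those 2 rose and 6 fell, with 2 rising and 7 falling when adjusted over the list alone (camera adjusted p = 3.66e-05, adjusted p = 0.265 with an estimated correlation). The division-site genes minC (-1.53 ± 0.16), minE (-1.45 ± 0.18) and minD (-1.33 ± 0.16) fell together, as did aspA, which encodes aspartase (-1.46 ± 0.28). Among other lists, 1 of 12 cold shock genes fell (cspE, -0.82), 1 of 28 anaerobic respiration genes fell (frdA, -1.09), and single members rose in the RpoS general stress list (yjbJ, 1.84), the replication and repair list (dnaQ, 1.01), the OxyR-activated list (mntH, a manganese transporter, 1.27), the cysteine and sulfate list (tcyP, 1.47) and the envelope stress list (yebE, 3.09). By locus tag, yjbJ (b4045) lies beside the SOS gene dinF (b4044), tcyP (b1729) beside ydjM (b1728) and yebE (b1846) near yebG (b1848). These single members do not stand for their lists. Adjusted over the list alone, the RpoS list had 3 rising, the cysteine list 1 rising and 1 falling, and the OxyR-repressed list 1 falling. The RpoS list had a median of 0.33 (25 measured, camera adjusted p = 0.000489, adjusted p = 0.518 with an estimated correlation) and the anaerobic respiration list one of -0.77 (camera adjusted p = 0.00302, adjusted p = 0.858 with an estimated correlation). Control replicate 2 was far above its fellows in narG, a member of the anaerobic respiration list (levels below).

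The e14 prophage, a cryptic phage in the icd gene, had no reads in recA730. All 26 annotated genes between icd and icdC (1196711 to 1211179) had 0 counts in all 3 recA730 libraries. With 3 counts over the recA730 group as the floor there (0.0871 CPM), the 19 of 20 measured list genes with more than 3 counts over the control group had, at the median, at least 5.21-fold lower levels in recA730. For jayE and ymfQ the bound (0.948) shows no fall. Of those 20 genes, 7 passed the test as fallen (4 without control replicate 2, control replicate 3, recA730 replicate 1 or recA730 replicate 2, and 12 by DESeq2) and 11 when adjusted over the list alone (camera adjusted p = 1.61e-21, adjusted p = 0.137 with an estimated correlation). icdC, a pseudogene that shares sequence with icd and lies just outside the interval, went the other way (5.22 ± 0.34). So did iraM, which follows icdC, at 0.351 pooled CPM in control and 6.62 in recA730. The Rac and Qin prophages did not follow: no member of either list (18 and 20 measured) passed the test, with a median log2 fold change of 0.05 for Rac and 0.36 for Qin (Qin camera adjusted p = 0.00605, adjusted p = 0.453 with an estimated correlation).

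**Figure D2:**
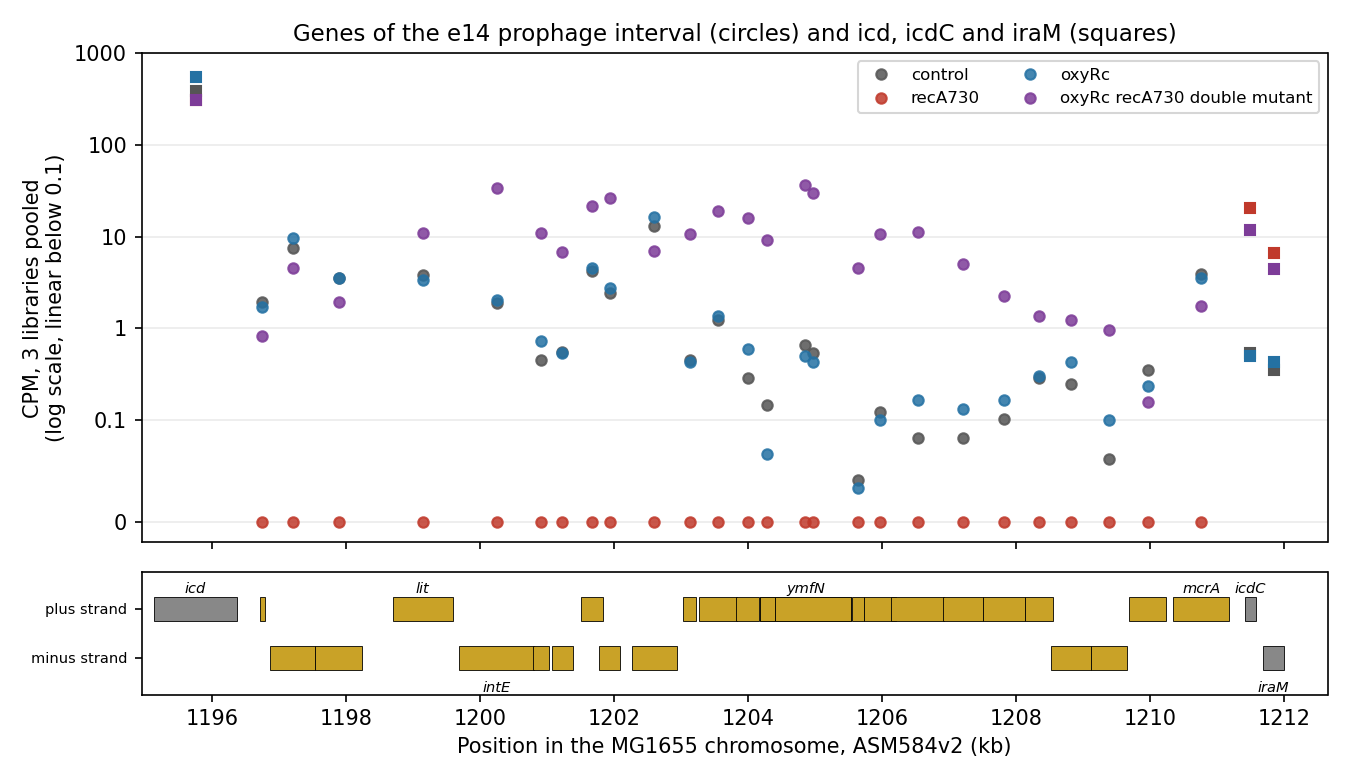
Pooled CPM of each gene of the e14 prophage interval (circles) and of icd, icdC and iraM (squares) by position in the chromosome in kb, with the genes on each strand drawn below. The 26 e14 genes are at 0 in recA730, while icdC is at 20.5 pooled CPM in recA730, 11.9 in the double mutant and 0.536 in control.

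No heat shock gene passed, and recA730 replicate 1 stood apart from its fellows in this list: dnaK, a chaperone gene, was at 1293 CPM there and at 110 and 129 CPM in replicates 2 and 3. The median log2 fold change of the 19 genes was 1.05 (camera adjusted p = 0.0221, adjusted p = 0.858 with an estimated correlation). In the control, narG, a nitrate reductase gene of the anaerobic respiration list, was at 341 CPM in replicate 2 and at 14.3 and 3.59 CPM in replicates 1 and 3. The flagellar list moved by a median of -0.42 in recA730 (46 measured, none passed, camera adjusted p = 0.0101, adjusted p = 0.858 with an estimated correlation). The ribosomal protein list moved by -0.17 (54 measured, none passed, camera adjusted p = 0.00605, adjusted p = 0.858 with an estimated correlation). The amino acid biosynthesis list moved by 0.29 (39 measured, camera adjusted p = 0.00605, adjusted p = 0.858 with an estimated correlation) and the TCA cycle list by -0.40 (14 measured, camera adjusted p = 0.0333, adjusted p = 0.858 with an estimated correlation), with no member of either passing. No member of the Fur-repressed iron uptake, SoxRS, Isc or acid resistance lists passed (43, 19, 8 and 12 measured), nor did any of the 3 OxyR-repressed genes or the 15 genes around oxyR.

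By edgeR's quasi-likelihood test, 127 of 4211 genes differed between recA730 and control (80 higher, 47 lower), 101 of them by at least 2-fold. The 47 lower genes were 19 without recA730 replicate 2, 26 without recA730 replicate 1 and 28 without control replicate 3. DESeq2 called 97 higher and 93 lower. Fitted with the libraries of these 2 genotypes alone, the count was 70, and without the e14 genes it was 117.

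In oxyRc against control, which asks what the active OxyR does on its own, the peroxide-defence genes rose. katG, the catalase gene, went from 85.03 ± 4.96 to 6053 ± 422 CPM (log2 fold change 6.15 ± 0.59, adjusted p = 0.000333) and oxyS, a small regulatory RNA, from 0.218 to 31.8 CPM (7.08 ± 0.69). grxA, a glutaredoxin gene, rose by 5.81 ± 0.51, dps, a DNA-binding ferritin gene, by 5.45 ± 0.47, trxC, a thioredoxin gene, by 4.42 ± 0.33, and the alkyl hydroperoxide reductase genes ahpF and ahpC by 4.10 ± 0.22 and 2.99 ± 0.19. The Suf iron-sulfur assembly genes were led by sufA (4.69 ± 0.74). Of the 21 measured OxyR-activated genes, 17 rose and 1 fell (ybjC, -1.93), with 18 rising and 1 falling when adjusted over the list alone (median 3.63). The camera test gave an adjusted p of 4.44e-59, and the call held with an estimated correlation (adjusted p = 0.0111). The SOS genes moved little: none of the 35 passed, with a median of 0.27 (camera adjusted p = 0.0255, adjusted p = 0.778 with an estimated correlation).

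**Figure D3:**
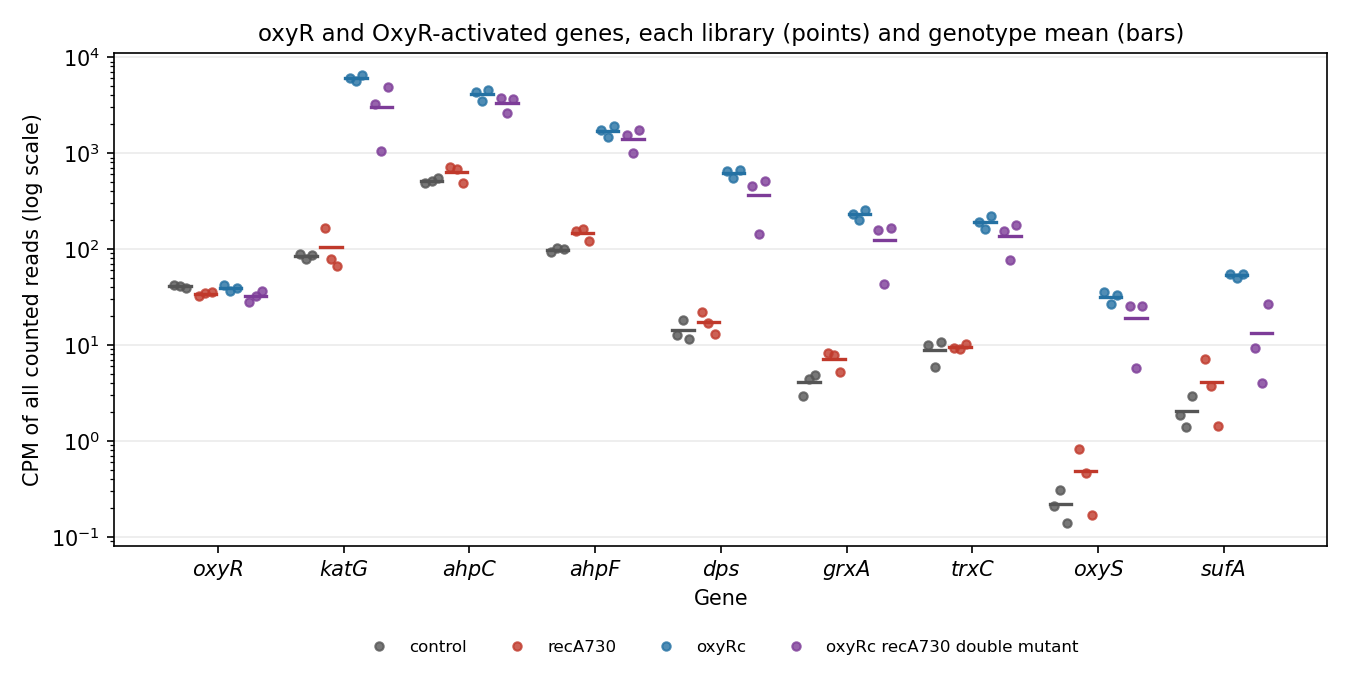
CPM on a log axis of oxyR and 8 OxyR-activated genes in each of the 12 libraries (points) with the mean of each genotype (bars). katG has a mean of 6053 CPM in oxyRc and 3061 CPM in the double mutant, where replicate 2 is the lowest at 1046 CPM.

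Flagellar genes fell in oxyRc. Of the 46 measured members 28 fell and none rose, with 32 falling when adjusted over the list alone and a median of -2.20 (camera adjusted p = 2.42e-37, adjusted p = 0.0985 with an estimated correlation). The hook genes flgD (-4.33 ± 0.85) and flgE (-3.87 ± 0.78) fell, as did flgB (-4.28 ± 0.70) and flgC (-4.57 ± 0.88). The count fell to 8 without oxyRc replicate 1, 6 without oxyRc replicate 3 and 15 without control replicate 2. With a filter of 10 CPM in 3 libraries it was 8. Other falls among the named genes were in cspC, an RNA chaperone gene (-1.63), the adjacent yobF (-1.69), nfsA, a nitroreductase gene (-1.68), fhuF (-1.69), bglJ (-2.17) and nupC, a nucleoside transporter gene (-0.87). Of the 3 OxyR-repressed genes, flu, which encodes antigen 43, rose (1.39 ± 0.31) and fhuF fell, so that 1 rose and 1 fell in either adjustment.

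Of the 43 Fur-repressed genes 4 rose in oxyRc, 5 when adjusted over the list alone, and the 4 were the ribonucleotide reductase genes nrdF (2.71), nrdH (2.72), nrdI (2.64) and nrdE (2.68). The median was 0.70 (camera adjusted p = 7.99e-06, adjusted p = 0.758 with an estimated correlation), and no member passed without control replicate 2, oxyRc replicate 1 or oxyRc replicate 3. None of the 8 Isc genes passed over all genes, but 8 rose when adjusted over the list alone (median 1.10, camera adjusted p = 9.26e-07, adjusted p = 0.430 with an estimated correlation). Of the 39 amino acid biosynthesis genes 5 rose, 11 when adjusted over the list alone, with argH at 3.51, argB at 0.97, hisB at 0.93, hisH at 0.79 and metE at 0.68 (camera adjusted p = 3.29e-06, adjusted p = 0.557 with an estimated correlation). That count was 1 without control replicate 2, oxyRc replicate 1 or oxyRc replicate 2, and 2 without control replicate 1 or oxyRc replicate 3. argH lies opposite to oxyS on the other strand, so its rise is uncertain, as are those of ybjM (4.82, opposite grxA) and yijF (4.15, opposite yijE), while yijE itself rose by 5.30. In the list of 15 genes around oxyR, which includes oxyR itself and its target oxyS, 3 rose (oxyS, argH and argB), 6 when adjusted over the list alone (camera adjusted p = 1.74e-05, adjusted p = 0.0470 with an estimated correlation). Other lists each held few calls: xthA, a base excision repair nuclease gene, rose in the replication and repair list (1.72) and acnA, an aconitase gene, in the SoxRS list (1.13), where nfsA fell. The srl genes rose (srlD 1.69, srlB 1.69, srlE 1.70, srlA 1.56), and 6 of 15 genes of the list around recA passed as risen (camera adjusted p = 3.89e-07, adjusted p = 0.123 with an estimated correlation).

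No heat shock gene passed over all genes and 1 rose when adjusted over the list alone (median 0.92, camera adjusted p = 5.37e-05, adjusted p = 0.641 with an estimated correlation), with dnaK at 857, 445 and 726 CPM in the oxyRc libraries and at 100, 94.7 and 201 CPM in the control libraries. No ribosomal protein gene passed (median -0.32, camera adjusted p = 1.02e-10, adjusted p = 0.641 with an estimated correlation).

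By edgeR, 156 of 4211 genes differed between oxyRc and control (109 higher, 47 lower), 115 of them by at least 2-fold. DESeq2 called 246 (147 higher, 99 lower), and without oxyRc replicate 3, oxyRc replicate 1, oxyRc replicate 2 or control replicate 1 the counts were 76, 77, 100 and 103, with 11, 12, 33 and 35 lower. Without control replicate 3 there were 79 lower.

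In the double mutant against control, both responses appeared together. tisB (5.77 ± 0.29), umuD (5.13 ± 0.33), recN (4.45 ± 0.22), umuC (4.04 ± 0.25), dinB (2.84) and polB (2.00) rose with katG (5.17 ± 0.56), grxA (4.90), yijE (4.71), dps (4.70), ahpF (3.84) and ahpC (2.70). Of the 35 SOS genes 30 rose, 31 when adjusted over the list alone (median 2.26, adjusted p = 0.00217 with an estimated correlation), and 4 of 4 translesion polymerase genes did. Of the 21 OxyR-activated genes 11 rose and 1 fell, with 18 rising and 1 falling when adjusted over the list alone (median 2.18, camera adjusted p = 2.69e-25, adjusted p = 0.0582 with an estimated correlation). DESeq2 called 17 of them as risen.

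The e14 genes in the double mutant were above their control level, the opposite of recA730: 16 of 20 rose, 17 rising and 1 falling when adjusted over the list alone (median 4.27, camera adjusted p = 2.36e-19, adjusted p = 0.166 with an estimated correlation). ymfN (5.82 ± 0.69) and aaaE (5.83 ± 0.70) overlap each other, so their reads cannot be assigned between them. Falls among the named genes were in srlD (-5.68 ± 0.20), srlB (-5.22), yobF (-2.04), bglJ (-1.97), cspC (-1.96), srlR (-1.87), tdcE (-1.86) and nfsA (-1.74). hdeA, an acid resistance gene, fell (-1.36, adjusted p = 0.0327), and soxS, the regulator gene of the superoxide response, rose (2.01 ± 0.42, adjusted p = 0.0153) from 2.23 to 9.24 CPM. The SoxRS list did not follow: of its 19 genes only soxS rose and only nfsA fell (median -0.07, camera adjusted p = 0.532). Its medians were 0.10 in the double mutant against recA730 and 0.08 against oxyRc. Flagellar genes fell in 5 of 46 cases, 32 when adjusted over the list alone (median -1.46, camera adjusted p = 1.31e-13, adjusted p = 0.355 with an estimated correlation). That count was 17 without double-mutant replicate 1, 0 without double-mutant replicate 2, 1 without control replicate 3, 2 without control replicate 2 and 3 without control replicate 1, while DESeq2 called 19 and limma-voom 21. Among the OxyR-activated genes, replicate 2 of the double mutant was lower than the other two: katG was at 3265, 1046 and 4873 CPM in replicates 1, 2 and 3. The e14 genes were also lower there, with 1530, 359 and 1609 CPM of protein-coding counts in sum.

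By edgeR, 256 of 4211 genes differed (189 higher, 67 lower), 161 of them by at least 2-fold. Without control replicate 3 the count was 165 (33 lower), without double-mutant replicate 1 it was 168 (41 lower), and fitted with these 2 genotypes alone it was 122. Without double-mutant replicates 2 and 3 there were 26 and 106 lower. DESeq2 called 211 higher and 133 lower. Scaling by library totals shifted the median of all genes by 0.13 and gave 218 higher and 27 lower.

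The double mutant against recA730 asks what the oxyR allele does where SOS is on, the comparison in the title of the series. Of the 35 SOS genes 2 fell and none rose, and these 2 were the genes of DNA polymerase V. umuD went from 70.2 ± 12.7 to 27.4 ± 10.7 CPM (log2 fold change -1.36 ± 0.25, 95% interval -1.90 to -0.81, adjusted p = 0.0116) and umuC from 174 ± 37.8 to 70.0 ± 24.6 CPM (-1.31 ± 0.22, adjusted p = 0.00631). umuC was at 131, 190 and 201 CPM in the recA730 replicates and at 59.7, 98.01 and 52.1 in those of the double mutant, so the 6 libraries did not overlap. Neither umuD nor umuC passed in a fit of these 2 genotypes alone. The shared fit takes its spread in part from the oxyRc libraries, which were closer to each other and are not in this comparison. The adjusted p values of umuD and umuC therefore depend on that shared spread. polB (-0.41, adjusted p = 0.189), dinB (-0.27, adjusted p = 0.663), recA (-0.46 ± 0.21, adjusted p = 0.435), lexA (-0.05, adjusted p = 0.957) and sulA, the division inhibitor gene (-0.47, adjusted p = 0.329), did not pass. The peroxide genes rose: katG (4.88 ± 0.56, with double-mutant replicate 2 the lowest of its genotype), dps (4.41 ± 0.45), yijE (4.47), trxC (3.85), ahpF (3.28), ahpC (2.41) and oxyS (5.32).

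As a list, the SOS genes had a median of -0.26 (camera adjusted p = 1.02e-05, adjusted p = 0.610 with an estimated correlation, fry adjusted p = 0.220). The 4 translesion polymerase genes had a median of -0.86, with 2 falling and 3 when adjusted over the list alone (camera adjusted p = 9.45e-06, adjusted p = 0.128 with an estimated correlation, fry adjusted p = 0.00908). Of the 21 OxyR-activated genes 10 rose and 1 fell, 12 and 1 when adjusted over the list alone (median 1.58, adjusted p = 0.0319 with an estimated correlation). All 20 measured e14 genes rose, at the median by at least 122-fold over recA730, where they were at 0 (adjusted p = 0.00619 with an estimated correlation). hdeA (-1.82), hdeB (-1.76) and wrbA (-1.40) fell, which were 2 of 12 acid resistance genes (camera adjusted p = 0.000988, adjusted p = 0.348 with an estimated correlation) and 1 of 25 RpoS genes (camera adjusted p = 5.08e-06, adjusted p = 0.323 with an estimated correlation). fhuF (-1.75), yobF (-1.63), nfsA (-1.59), cspC (-1.55), tsx, a nucleoside channel gene (-1.09), and rimK (-0.62) fell as well, while soxS rose (2.20) and flu rose (1.63). The Fur-repressed genes had a median of -0.69 and none passed (camera adjusted p = 3.22e-07, adjusted p = 0.804 with an estimated correlation).

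By edgeR, 89 of 4211 genes differed (74 higher, 15 lower), 80 of them by at least 2-fold, and 59 without the e14 genes. DESeq2 called 91 higher and 36 lower, and with library totals as scaling 9 were lower. Fitted with these 2 genotypes alone, the count was 18, with 0 SOS genes falling, 3 OxyR-activated genes rising and 0 e14 genes rising, and the adjusted p was 0.130 for umuC and 0.131 for umuD; umuD also missed the threshold without recA730 replicate 2 (0.0572) or double-mutant replicate 1 (0.0754).

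The double mutant against oxyRc asks what the recA allele does where OxyR is on, and the SOS genes rose here as well: 31 of 35 rose, 31 when adjusted over the list alone (median 1.73, adjusted p = 0.00332 with an estimated correlation), with recA at 3.95, lexA at 1.57, tisB at 5.38, umuD at 5.21 and yebF at 4.21. The srl genes fell furthest, with srlD at -7.37 ± 0.21, srlB at -6.90, gutM at -4.72, srlR at -2.87 and srlA at -2.52, and 9 of 15 genes of the list around recA fell and 3 rose (recA itself, recX and mltB), 10 and 3 when adjusted over the list alone (adjusted p = 0.0185 with an estimated correlation). The e14 genes were higher, 13 of 20 rising and 17 rising and 1 falling when adjusted over the list alone (median 3.85, camera adjusted p = 3.50e-18, adjusted p = 0.224 with an estimated correlation), with ymfN at 6.20 and aaaE at 6.12.

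The 14 TCA cycle genes had a median of -0.90, with 2 falling (icd, -0.81, and mdh) and 6 when adjusted over the list alone (camera adjusted p = 1.92e-06, adjusted p = 0.496 with an estimated correlation). The 43 Fur-repressed genes had a median of -1.10, with 1 falling (bfd, -1.10) and 21 when adjusted over the list alone (camera adjusted p = 3.75e-13, adjusted p = 0.508 with an estimated correlation). The OxyR-activated genes had a median of -0.54 and none passed (camera adjusted p = 7.11e-05, adjusted p = 0.508 with an estimated correlation). Double-mutant replicate 2 was low in OxyR-activated genes, with a median ratio to replicate 1 of 0.45, against 1.04 for replicate 3. soxS rose by 2.21. By edgeR, 186 of 4211 genes differed (131 higher, 55 lower), 104 of them by at least 2-fold. That count was 433 without double-mutant replicate 3, with 193 higher and 240 lower, and 83 to 104 when any other library of these 2 genotypes was left out (oxyRc replicates 1, 2 and 3 gave 89, 83 and 104, double-mutant replicates 1 and 2 gave 95 and 103), and with library totals as scaling the split was 120 higher and 27 lower. DESeq2 called 183 higher and 168 lower, and limma-voom 130 and 100.

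The interaction asks whether the effect of 1 allele depended on the other. In srlD the effects did not add up: it was at 189 CPM in control, 4.72 in recA730, 613 in oxyRc and 3.69 in the double mutant, an interaction of -2.04 ± 0.24 (adjusted p = 0.00855). It was low in both genotypes with the recA730 allele (-0.35 between them, adjusted p = 0.515), where a marker linked to recA is not excluded. It was the only gene past the threshold by edgeR, where 466 genes had an unadjusted p under 0.05, while DESeq2 called 50 and limma-voom 1. In umuC (-1.54, adjusted p = 0.140) and umuD (-1.28, adjusted p = 0.428) the interaction did not pass. No SOS gene passed, 2 fell when adjusted over the list alone, and the list median was -0.45 (camera adjusted p = 9.78e-09, adjusted p = 0.229 with an estimated correlation). The 4 translesion polymerase genes had a median of -1.01, and 4 fell when adjusted over the list alone (camera adjusted p = 3.48e-05, adjusted p = 0.214 with an estimated correlation, fry adjusted p = 0.0358). The e14 list had a bounded median of at least 6.36 with 19 genes rising when adjusted over the list alone (adjusted p = 0.0116 with an estimated correlation). That value rests on genes at 0 counts in recA730. The OxyR-activated list had a median of -1.03 (camera adjusted p = 2.15e-09, adjusted p = 0.229 with an estimated correlation). Double-mutant replicate 2, which was lower than its fellows in OxyR-activated genes, enters that median. Without double-mutant replicate 2 the count of genes past the threshold was 22, without double-mutant replicate 3 it was 20, without control replicate 2 it was 3 and without recA730 replicate 1 it was 2.

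Across the 4211 genes, which are not independent replicates, the recA730 effects in the 2 oxyR backgrounds had a Pearson correlation of 0.128 and a Spearman correlation of 0.214, and the oxyRc effects in the 2 recA backgrounds 0.248 and 0.147. These pairs of effects share no library. Of the 80 genes higher in recA730 and the 131 higher in the double mutant against oxyRc, 62 were shared, against 2.49 for independent lists. Among the lower genes 12 were shared (47 and 55, 0.614 for independent lists). For the oxyRc effect 39 of the 109 and 74 higher genes were shared (1.92 for independent lists) and 7 of the 47 and 15 lower genes (0.167). Without e14 genes the correlations were 0.449 and 0.442.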

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

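The tests of prophage loss and of repression by the recA730 allele were chosen after the result was seen, and those of depth and of other splits were not. srlD was singled out because the 2 alleles did not add up, with an interaction of -2.04 in log2 (adjusted p = 0.00855) and levels of 189, 4.72, 613 and 3.69 CPM in control, recA730, oxyRc and the double mutant. It was low in both genotypes with the recA730 allele, and no test here separates an effect of the allele from a disruption of srl by a marker linked to recA in both strains. In that case the interaction would come from how the strains were built.

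The e14 prophage list had an interaction of at least 6.36 in log2 at the median (floor of 3 counts). Its genes were at 0 in recA730 and high in the double mutant. In oxyRc against control, 0 of its 20 measured genes passed (median 0.16). If the recA730 strain lacks the prophage, the interaction would be a difference between strains and not a response to the oxyR allele. Low depth is argued against, since 0% of 743 genes of the same control abundance were at 0 counts in all 3 recA730 libraries. Repression that follows the recA730 allele is argued against by the double mutant, which carries that allele and stood above control by a median of 4.27. Loss of the prophage from the recA730 strain stays open: that 0 of the 26 e14 genes had a read there is the pattern itself. icdC, next to the excision site, rose by 5.22 in recA730 but also by 4.42 in the double mutant, where the e14 genes had reads. The double-mutant value comes from another strain, so this test does not argue against loss in recA730. An earlier version of that test counted the missing reads as evidence for loss and was replaced.

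Other splits of the same libraries were counted for each number of differing genes. The genotype split was 1 of 10 in each of the 5 pairs, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 127 and 5 for recA730 against control, 156 and 0 for oxyRc against control, 256 and 118 for the double mutant against control, 89 and 0 against recA730, and 186 and 0 against oxyRc. For the interaction, 4 of 100 drawn splits of the 12 libraries, the real one included, gave as many genes as the real 1, the highest other giving 4. Whether chance can be excluded stays open for that count, although the share is under the 0.05 set beforehand. Splits that mix genotypes turn their differences into spread, also in the 5 pairs, so their low counts are partly fixed in advance. For the interaction the biological coefficient of variation was 0.265 to 0.352 in the others against 0.218, which was looked at after the count was seen. The split with 118 set control replicates 1 and 3 and double-mutant replicate 3 against the rest. On the main axis of spread within genotypes these were at -5.14, -18.8 and -15.6. Control replicate 2 and double-mutant replicates 1 and 2 were at 23.9, 8.32 and 7.24.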

How the results depend on the processing

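The fit without e14 genes, and all alternatives for the counts of list members that rose or fell, were chosen after seeing the data. The differing genes of the double mutant against oxyRc went from 131 higher and 55 lower to 193 higher and 240 lower without double-mutant replicate 3. Over 168 named gene comparisons and 2658 alternative values, 2418 kept their direction and side of the threshold, 240 kept their direction but no longer passed, and 0 reversed. These comparisons were only those that passed in the main fit, plus recA, lexA and oxyR. Many were picked for large changes without overlap between libraries, which makes a reversal unlikely from the start. Fits with only the genotypes compared gave 70 (recA730 against control), 122 (double mutant against control), 18 (against recA730) and 415 (against oxyRc) differing genes, against 127, 256, 89 and 186. At an adjusted p under 0.01 the counts were 71, 66 (oxyRc against control), 130, 51 and 83, by construction. With a 2-fold limit they were 161 (double mutant against control) and 104 (against oxyRc). DESeq2 gave 246 (oxyRc against control), 351 (double mutant against oxyRc) and 50 (interaction). The interaction was 12 without TMM and 2 with the stricter filter. The stricter filter, which tests 2341 genes, gave 52 for the double mutant against recA730, and the fit without e14 genes gave 59. The cause was not tested for the DESeq2, scaling and 2-genotype values.

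Leaving out 1 library gave 96 to 147 genes for recA730 against control, 76 to 202 for oxyRc against control, 165 to 261 for the double mutant against control, 64 to 103 against recA730, 83 to 433 against oxyRc and 1 to 22 for the interaction. The list test of SOS genes in the double mutant against recA730 was lost with an estimated correlation (0.610) and with fry (0.220), and that of the translesion genes with an estimated correlation (0.128). The correlation of the recA730 effect was 0.466 with the stricter filter, 0.449 without e14 genes and 0.0455 to 0.222 without 1 library. That of the oxyRc effect was 0.447, 0.442 and 0.138 to 0.318. The replicate number as a block gave 144, 143, 245, 80, 187 and 4 genes in the order of the comparisons. The numbers do not pair the libraries: 6 of 18 same-numbered pairs had a correlation of deviations over 0.1 (from -0.354 to 0.423) and 5 of 12 libraries correlated best with their own number. At this depth and with a spread shared by all genotypes, 10.4% of simulated 1.5-fold changes were recovered, all placed in genes above a minimum expected count.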

Other observations

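The tests in this part were chosen after the results were seen. The genes in this paragraph were also chosen after their values were seen. In the double mutant, 3 genes of the cryptic type II secretion cluster, which was not tested as a list, rose: gspM went from 1.38 CPM in control to 10.1 (log2 fold change 2.89 ± 0.29, adjusted p = 5.04e-05 by edgeR), gspO rose by 1.57 (adjusted p = 0.000366) and gspL by 1.22 (adjusted p = 0.00437), while gspD (0.24, adjusted p = 0.623) and gspK (0.15, adjusted p = 0.798) did not pass and gspM was at 1.45 in recA730 and 1.57 in oxyRc. The interaction for gspM was 2.61 (adjusted p = 0.0581), which did not pass. pflC and pflD rose by 4.04 and 3.23 in oxyRc and by 4.07 and 3.11 in the double mutant. By locus tag, pflC (b3952) and pflD (b3951) lie close to oxyR (b3961), so a marker linked to oxyR is not excluded. In double-mutant replicate 2, where OxyR-activated genes were lower, they were at 13.4 and 15.9 CPM. Their means in replicates 1 and 3 were 12.1 and 16.45 CPM. folE, a folate synthesis gene, rose by 1.87 in oxyRc, with its neighbour yeiB (2.22), aes (2.23), uof (1.82) and trxB, the thioredoxin reductase gene (1.41). The protease adaptor and subunit genes clpS and clpA rose by 1.62 and 1.77 in oxyRc.

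Replicate 2 of the double mutant was lower than its fellows in OxyR-activated and e14 genes, with e14 genes at 359 CPM of protein-coding counts in sum against 1530 and 1609. Low depth is argued against, as it held 4083911 protein-coding counts against 3992488 in replicate 1. The main axis of spread within genotypes, whose nature was not tested, is argued against as well. Replicates 1 and 2 lie close on that axis (8.32 and 7.24), yet the median ratio of replicate 2 to 1 over OxyR-activated genes was 0.45 (1.04 for replicate 3 to 1). Mixture with recA730 cells would leave the same share of each difference, and 15 of 61 genes outside e14 that differed at least 2-fold from recA730 in a fit without replicate 2 lay nearer the other double-mutant libraries than a share of 0.24 allows, with 0 nearer recA730. That share is the median over the e14 and OxyR-activated genes. The 12 OxyR-activated genes are also among the 61, and ahpC, ahpF and ybjC are among the 15. That criterion replaced an earlier one after its value was seen: the median share left was 0.238 for e14 genes, 0.257 for OxyR-activated genes and 0.423 for other genes, which had decided nothing, so mixture is argued against only as the whole explanation. No biological explanation was tested.

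Genes on the opposite strand just downstream of strongly risen genes (recA730 or oxyRc against control) rose as well, as argH beside oxyS did. Counts that include reads of the opposite strand are a candidate explanation: of 10 such convergent neighbours 8 rose, with a median log2 fold change of 1.49, against a 95th percentile of 0.188 over 10000 random draws. Of the draws 0 were as high, and the median was 0.85 for the 7 neighbours left without the 3 seen first. Shared regulation stays open only in a narrower form: convergent genes start at their far ends, so no promoter region between them can serve both. Whether a neighbour follows the same regulator from its own start was not tested. The 9 divergent upstream neighbours (median 0.408, interquartile range 1.16) are different genes, mostly beside other risen genes. Their median cannot decide why the convergent neighbours rose. An earlier version that counted reciprocal pairs more than once and kept genes at the e14 junction had argued against shared regulation, and was replaced once that error was seen.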
